A study of Mus musculus with 10 samples.

How the data were processed

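RNA sequencing of the peri-pulmonary vein part of the left atrium was processed for 10 libraries, 4 Ctrl and 6 CKO, each from a different mouse per the study's description. The labels give a genotype and a replicate number and no batch, and correlations between the deviations of same-numbered Ctrl and CKO libraries (0.0313, 0.0876, -0.319 and 0.0894) gave no sign that the numbers pair animals. Per the study's description RNA was depleted of ribosomal RNA, whereas the sample labels give polyA RNA as the molecule, so that levels of transcripts without a polyA tail, such as many histone transcripts, depend on a step that is not settled. Libraries were made with a TruSeq kit and sequenced on a HiSeq4000. The submitters' processing notes name TopHat2 2.1.1 for alignment to mm10, BamTools for the removal of poorly aligned, duplicated and unmapped reads, StringTie 1.3.3 for assignment to transcripts, and edgeR 3.18.1 and limma 3.32.10 in R 3.4.0 for the authors' tests. Per the file headers StringTie was run on the Ensembl annotation of GRCm38 without assembling new transcripts.

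3 kinds of deposited file were read. The deposited gene table holds estimated counts, whole numbers that are not divided by depth or length, for 54532 Ensembl genes. In all 10 libraries each value equalled the sum over a gene's transcripts of coverage times length over a read length of 50, rounded up per transcript, exactly and for all 54532 genes. Such expected counts are made from coverage, so they are not raw read numbers. The deposited transcript files give, per the file headers and their values, coverage in mean reads per base for transcripts and exons, and TPM. The deposited table of the authors gives log2 fold changes and, per gene, a p-value and false discovery rate for 13646 genes in 3 comparisons; its filter and model are not stated. The gene table also has 10 columns of left atrial appendage libraries of an earlier study, which were not used here, and the authors' own fold changes were described instead. Genes of the Y chromosome and of the mitochondrial genome, and the alpha globin genes Hba-a1 and Hba-a2, were at 0 in every library.

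Summed counts per library ran from 8602794 to 10040808, and TMM factors from 0.951 to 1.05. Replicates differed by far more than counting error, with a chi-square per degree of freedom of at least 10.1 between libraries of a group, a value that abundant genes dominate. Gene by gene, counting variance in the group with the lower mean exceeded the fitted dispersion between animals in 5.23% of tested genes. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (17752 of 33196 with any count), scaled by TMM and tested with the quasi-likelihood F test for CKO against Ctrl with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values use TMM-scaled library sizes, and standard errors are the fold change over the square root of F. Simulated counts with the fitted means and dispersions were tested in the same way. Of 200 changed genes, 2.99% with a 1.5-fold, 38.8% with a 2-fold and 77.3% with a 4-fold change were found, and 6 of 85 calls (7.06%) were false.

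There were 39 gene lists, written from general knowledge of the tissue, of which 38 had at least 5 tested members and the mitochondrially encoded list had 0. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. In simulated data the changed list was found and 0 of 37 unchanged lists were called. The simulated genes were drawn independently, so this does not test the preset correlation where genes of a list vary together. Genes were named by rule: Tbx5; the 12 highest and 12 lowest fold changes among genes past the threshold with a mean CPM of 1 or more and no overlap between groups, without names that are only model numbers; up to 4 called members of each list by adjusted p, or 2 by mean CPM where none was called; and the 10 highest and 10 lowest genes of the authors' region comparison. These choices, the lists and the alternatives were fixed before the data were examined, apart from those named as chosen later. Of 404 genes that met the filter, this named 99.

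Coverage of the 9 exons of the main Tbx5 transcript was divided by the median exon of the same library. It was compared by an exact two-sided permutation test over all 210 relabellings, adjusted over the exons. Simulated data with 1 exon lowered gave 96 of 100 found and 9 of 800 false calls. The simulated noise was smaller than the observed spread of exon 3 (1.2 ± 0.356 in Ctrl and 0.452 ± 0.174 in CKO), so the share found is likely too high for these data. Exon positions and coding parts were taken from the reference annotation of the same genome build. Regional genes of the authors' table were compared with the genes called here by two-sided Fisher's exact tests over the 13628 genes in both, adjusted over 4 tests, and by camera; of simulated gene sets 5 of 200 independent pairs and 200 of 200 pairs sharing 40 genes were called. Since the Ctrl libraries enter both comparisons, the covariance they alone give was computed from their variance and from 20 simulations; the controls were not divided, because the regional fold changes come from the authors' table.

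Alternatives were RLE, upper-quartile and library-size scaling, no filter, a minimum of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, robust edgeR, thresholds of 0.01 and 0.1, glmTreat at a fold of 1.2, replicate number as a block, a surrogate variable from sva 3.50.0, limma on log2 TPM with pseudocounts of 1 and 0.1, each library left out in turn, other exon scalings and other thresholds for the authors' comparison. Added after the data were seen were fits without Ctrl 3 and CKO 4, which hold airway transcripts, with Xist level as a covariate, separately at each Xist level and with an interaction, and exon coverage summed over transcripts. The counts of called genes and of lists past camera, at the preset and the estimated correlation, were repeated for 100 of the 210 divisions into 4 and 6. The other tests were not repeated in this way. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for exon tests and figures.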

Results

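RNA was sequenced from the part of the left atrium that surrounds the pulmonary veins, whose walls carry sleeves of atrial muscle, in 10 adult mice. There were 4 controls (Ctrl) and 6 mice with an induced deletion of Tbx5 (CKO), the gene of a T-box transcription factor that acts in atrial development and rhythm. All animals were homozygous for a tamoxifen-inducible Cre recombinase at the Rosa26 locus, Ctrl animals had wild-type Tbx5, and CKO animals had a floxed Tbx5 allele on both chromosomes. Both groups thus carried the recombinase and received tamoxifen. Tamoxifen was injected on 3 days at 6 weeks of age and the tissue was collected 1 week after treatment. Summed gene counts were 9466787, 9166237, 8602794 and 8670555 in Ctrl 1 to 4, and 9201580, 10040808, 9498923, 9458935, 9479104 and 8963537 in CKO 1 to 6. Between 12.6% and 17.6% of a library's count fell on its 10 most abundant genes. Transcripts of the airway lining were abundant in Ctrl 3 and CKO 4: the secretory protein gene Scgb1a1 stood at 862 and 1452 CPM (counts scaled by library size) in these, against at most 42.0 CPM in any other library. Xist, the RNA that coats the inactive X chromosome, was at 1002 to 1314 CPM in Ctrl 1 and 2 and CKO 1 to 3, and at 1.51 to 6.22 CPM in Ctrl 3 and 4 and CKO 4 to 6. Values below are means ± SD with n = 4 Ctrl and n = 6 CKO, and positions are on GRCm38. Adjusted p-values come from edgeR's quasi-likelihood test with the Benjamini-Hochberg method over all tested genes unless another test is named.

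The Tbx5 transcript itself was examined for the effect of the induced recombination. Exon 3 of Tbx5 was under-represented in every CKO library. General knowledge of this floxed allele, and not the labels, places exon 3, a part of the DNA-binding T-box, between its loxP sites. Coverage of exon 3 was 1.2 ± 0.356 times that of the median exon in Ctrl and 0.452 ± 0.174 times in CKO. The lowest Ctrl value was 0.903 and the highest CKO value 0.618. Total Tbx5 RNA did not drop: the gene count went from 134 ± 31.6 to 268 ± 105 CPM (log2 fold change 1.00, SE 0.29), but this missed the threshold (adjusted p = 0.101). Tbx5 (ENSMUSG00000018263) lies on chromosome 5 from 119832668 to 119885219 on the plus strand. Exon 3 of its main transcript ENSMUST00000018407 is a coding exon of 95 bases from 119838696 to 119838790, a length that leaves a remainder of 2 when divided by 3. Across 27 alternative settings the Tbx5 fold change was 0.72 to 1.19 on the log2 scale, with adjusted p between 0.00963 and 0.302. It passed 0.05 in 2 of them, DESeq2 (1.02, adjusted p = 0.00963) and a fit with Xist level as a covariate (0.94, adjusted p = 0.0116). In the authors' deposited table the change in this tissue was 0.99 with a false discovery rate of 0.0117.

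Among the 9 exons of that transcript, exon 3 was the only exon that passed the threshold (exact two-sided permutation test over 210 relabellings of 4 against 6 libraries, p = 0.00476, the smallest possible, adjusted p = 0.0429). When coverage was summed over the annotated transcripts that share an exon, exon 3 was at 1.09 ± 0.103 in Ctrl and 0.464 ± 0.148 in CKO (adjusted p = 0.0107 in the exact test). CKO libraries lay between 0.203 and 0.621 and the lowest Ctrl library at 0.994. In this sum exon 1, which is untranslated, was lower in CKO (0.211 ± 0.0461 and 0.127 ± 0.0141; exact permutation adjusted p = 0.0107). Exon 8 (0.936 ± 0.0863 and 1.22 ± 0.0889) and exon 9, which holds the end of the coding sequence (0.467 ± 0.0163 and 0.654 ± 0.0708), were higher with the same p. Scaled to library size, main-transcript coverage of exon 3 was 2.49 ± 1.01 in Ctrl and 1.77 ± 0.951 in CKO, a ratio of 0.711, whereas that of exon 8 was 2.73 ± 0.774 and 5.78 ± 2.12, a ratio of 2.11. With 1 control left out, a single exon of 9 cannot reach an adjusted p under 0.107, and with 1 CKO library left out under 0.0714. Divided by the library total instead of the median exon, 0 of 9 exons passed.

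**Figure D1:**
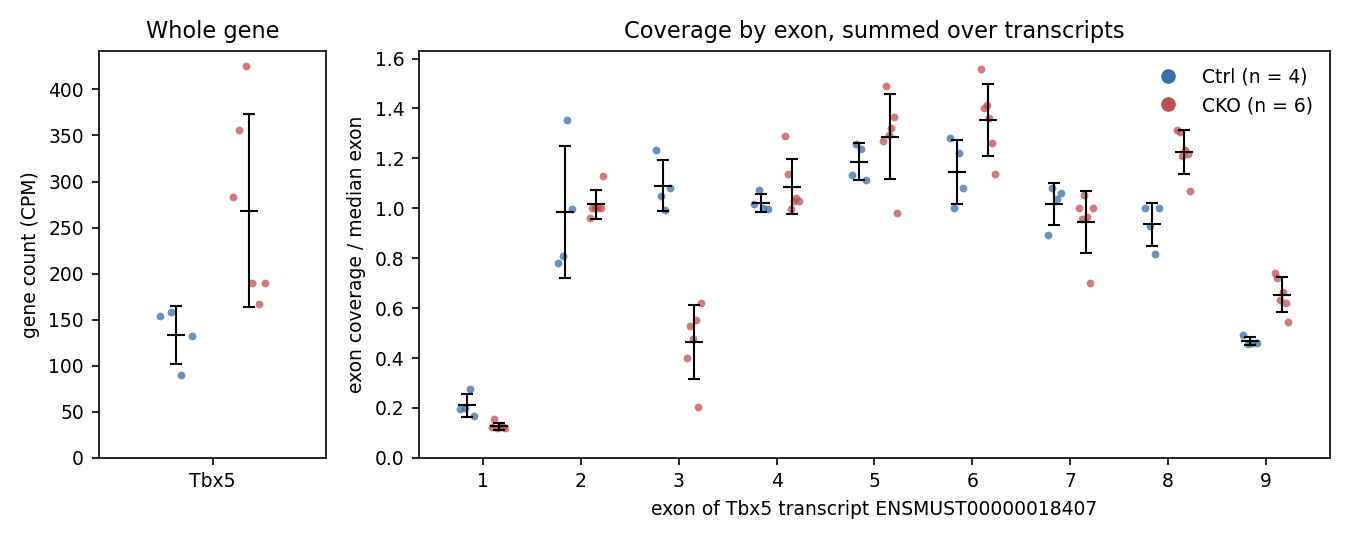
Tbx5 gene count in CPM (left) and coverage of each of the 9 exons of Tbx5 transcript ENSMUST00000018407, summed over transcripts that share the exon and divided by the median exon (right), for 4 Ctrl (blue) and 6 CKO (red) libraries; points are libraries and bars are mean ± SD. Exon 3 lies at 0.203 to 0.621 in CKO, below the lowest Ctrl library at 0.994, while the gene count is 134 ± 31.6 CPM in Ctrl and 268 ± 105 CPM in CKO.

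The main comparison asked which transcripts of the tissue around the pulmonary veins differ after deletion of Tbx5. Genes of atrial muscle identity were lower in CKO as a set, and genes of muscle stress were higher, by camera at a preset and at an estimated correlation. Some genes of impulse conduction were lower, and some of the contractile filament and of cell division were higher. These 3 lists passed camera at the preset correlation only (adjusted p = 0.112, 0.166 and 0.129 with an estimated correlation). Ranked here are called genes with a mean CPM of 1 or more, no overlap between the groups and a name that is not only a clone number. Outside these limits larger changes were called, such as that of Kntc1 (5.55, from 0.0819 to 4.47 CPM). Within them the largest decrease was that of Sbk3, a heart-enriched kinase gene (ENSMUSG00000085272, chromosome 7, 4965260 to 4971168, minus strand), from 284 ± 58.0 to 6.59 ± 3.62 CPM (log2 fold change -5.42, SE 0.38, adjusted p = 8.82e-05). The largest increase within these limits was that of Acta1, the skeletal alpha-actin gene that the stressed heart re-expresses (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751, minus strand), from 4.34 ± 0.518 to 115 ± 43.7 CPM (log2 fold change 4.72, SE 0.37, adjusted p = 8.82e-05). In total 497 of 17752 tested genes passed an adjusted p of 0.05, 274 higher and 223 lower in CKO. Of these, 307 changed by at least 1 on the log2 scale, 167 higher and 140 lower. In 460 the CKO and Ctrl values did not overlap. This is a separation that chance gives to 0.952% of genes and that 1016 of the tested genes showed. The share of called genes that were higher was 55.1%, and 44.1% when counts were scaled by library size only. The median log2 fold change of all tested genes was -0.03.

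Atrial muscle genes fell as a set. Of 30 tested genes of the atrial cardiomyocyte list, 15 fell and 0 rose, and 20 passed when adjusted over the list alone (1 higher and 19 lower). The median log2 fold change of the list was -0.86 (camera adjusted p = 5.49e-39; adjusted p = 0.00650 with an estimated correlation). Myl7, the atrial regulatory myosin light chain (ENSMUSG00000020469, chromosome 11, 5896637 to 5898782, minus strand), fell from 5300.5 ± 1588 to 870.3 ± 195 CPM (log2 fold change -2.61, SE 0.21, adjusted p = 0.000116). The atrial essential light chain Myl4 fell from 4698 ± 1031 to 2521 ± 417 CPM (-0.90), a gene named after its values were seen. Other decreases on the log2 scale were those of the kinase gene Sbk2 (-3.37, SE 0.16, adjusted p = 5.35e-06), the filament protein gene Mybphl (-1.28, SE 0.09), Fgf12, whose product binds sodium channels (-1.2, SE 0.09), and the calcium pump inhibitor sarcolipin, Sln (-0.96, SE 0.18). Nppa, the atrial natriuretic peptide gene and also chosen after its values were seen, was at 3445 ± 399 CPM in Ctrl and 1572 ± 666 CPM in CKO and missed the threshold (-1.13, adjusted p = 0.0984). Leaving out any 1 library gave 12 to 15 lower and 0 higher list members, and without the airway-containing Ctrl 3 and CKO 4 there were 14.

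Some conduction and channel genes fell too, though none of their lists passed camera with an estimated correlation. Among 24 tested sinoatrial node and conduction markers 7 fell and 0 rose, with 10 past the threshold when adjusted over the list alone (2 higher and 8 lower). These markers had a median of -0.58 (camera adjusted p = 4.75e-11; adjusted p = 0.112 with an estimated correlation). Without Ctrl 3 there was also 1 higher. The adhesion molecule Cntn2, a marker of the conduction system (ENSMUSG00000053024, chromosome 1, 132509427 to 132543256, minus strand), fell from 89.1 ± 33.9 to 4.03 ± 1.46 CPM (log2 fold change -4.46, SE 0.33, adjusted p = 8.82e-05). Hcn4, the pacemaker channel (ENSMUSG00000032338, chromosome 9, 58823412 to 58863175, plus strand), fell from 36.7 ± 11.3 to 7.67 ± 3.16 CPM (log2 fold change -2.25, SE 0.29, adjusted p = 0.00252). Cpne5 (-4.0), the muscarinic receptor Chrm2 (-0.83) and the calcium channel subunit Cacna2d2 (-1.96) were lower as well. Of 25 tested genes of sodium channels and gap junctions 4 fell and 1 rose, with 8 past the threshold when adjusted over the list alone (2 higher and 6 lower). As a set they had a median of -0.31 (camera adjusted p = 0.00140; adjusted p = 0.230 with an estimated correlation). Gja5, the atrial gap junction protein connexin 40 (ENSMUSG00000057123, chromosome 3, 96904693 to 97077416, plus strand), fell from 79.0 ± 10.7 to 7.39 ± 5.28 CPM (log2 fold change -3.42, SE 0.43, adjusted p = 0.00232). Scn10a (-2.71, SE 0.41) and Fgf12 fell too. Pkp2, a desmosome gene, rose (1.00, SE 0.11).

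Among 30 tested potassium and pacemaker channel genes 4 fell and 0 rose, with 9 past the threshold when adjusted over the list alone (1 higher and 8 lower). They were Hcn4, Kcnv2 (-1.42) and the subunits of the acetylcholine-activated potassium channel Kcnj5 (279 ± 65.0 to 75.3 ± 25 CPM, -1.89) and Kcnj3 (210.2 ± 36.9 to 76.5 ± 21.5 CPM, -1.46). This list's median was -0.03 (camera adjusted p = 0.00617; adjusted p = 0.489 with an estimated correlation, and 0.084 with replicate number as a block). Of 39 tested genes at loci associated with human atrial fibrillation 7 fell and 1 rose, with 15 past the threshold when adjusted over the list alone (5 higher and 10 lower). The genes at these loci had a median of -0.12 (camera adjusted p = 0.00930; adjusted p = 0.489 with an estimated correlation, and 0.0574 with replicate number as a block). The member that rose was Hand2, a heart and sympathetic transcription factor (1.2, SE 0.23). Hand2 and Tbx3, a T-box factor of the conduction system (-1.21, adjusted p = 0.0493), were the called members among 35 tested cardiac transcription factors (5 adjusted over the list alone; camera adjusted p = 0.575). Of 36 tested calcium handling genes 1 rose, the skeletal calsequestrin Casq1 (2.06), and 2 fell, Cacna2d2 and Sln (3 adjusted over the list alone; camera adjusted p = 0.721). Ryr2, the calcium release channel, looked up after the other values were seen, did not pass (-0.89, adjusted p = 0.134). Without Ctrl 3 there were 2 higher transcription factors. Hand2 missed the threshold without Ctrl 1 or Ctrl 4 (adjusted p up to 0.0811) and Kcnv2 without Ctrl 2 (0.0524). Tbx3 passed only in the full set and without Ctrl 3 or CKO 3, with adjusted p up to 0.155 without Ctrl 2.

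The contractile list held genes that rose and genes that fell. Of 44 tested sarcomere and Z-disc genes 13 rose and 4 fell, with 29 past the threshold when adjusted over the list alone (23 higher and 6 lower). The whole sarcomere list had a median of 0.48 (camera adjusted p = 4.62e-09; adjusted p = 0.166 with an estimated correlation). Myl3, the ventricular essential light chain (ENSMUSG00000059741, chromosome 9, 110741861 to 110769798, plus strand), rose from 48.3 ± 20.2 to 493 ± 141 CPM (log2 fold change 3.35, SE 0.31, adjusted p = 0.000382). Desmin, Des (0.85), the actin-capping Lmod2 (0.88) and the stress-responsive Xirp1 (1.65) also rose, and the members that fell were Myl7, Myl4, Mybphl and Neb. Without Ctrl 4 the list gave 8 higher, and without Ctrl 2 it gave 2 lower. Of 10 tested skeletal muscle markers 5 rose and 0 fell, with 6 past the threshold when adjusted over the list alone (5 higher and 1 lower). This set had a median of 0.44 (camera adjusted p = 1.29e-07; adjusted p = 0.00650 with an estimated correlation). They were Acta1, Casq1, Mybpc2 (1.2), the creatine kinase Ckm (0.67) and, named after its values were seen, Myl1 (0.95, 399.9 ± 118 to 771 ± 181 CPM). This count was 2 without Ctrl 1, CKO 1, CKO 2 or CKO 6 and 3 without Ctrl 2, Ctrl 4, CKO 3 or both Ctrl 3 and CKO 4. Without CKO 4 alone 4 skeletal markers were called higher and 1 lower. Of 22 tested ventricular cardiomyocyte genes 4 rose, Myl3, Lmod2, Cav3 (0.82) and Ckm, and 1 fell, Kcnv2, with 7 past the threshold when adjusted over the list alone. Ventricular genes had a median of 0.33 (camera adjusted p = 7.81e-05; adjusted p = 0.129 with an estimated correlation). The count was 2 higher without Ctrl 1, Ctrl 2, Ctrl 4, CKO 1 or CKO 2, or both Ctrl 3 and CKO 4, and 0 lower without Ctrl 2. The heavy chain genes Myh6 (0.30, adjusted p = 0.483) and Myh7 (1.08, adjusted p = 0.341), looked up after the other values were seen, did not pass. Des missed the threshold without Ctrl 2 or Ctrl 4 (adjusted p up to 0.0593). Cav3 did so without any 1 control, CKO 1 or CKO 2 (up to 0.0859), and Mybpc2 without Ctrl 1, Ctrl 3, CKO 1, CKO 2 or CKO 6 (up to 0.0784). Ckm passed only in the full set and without Ctrl 3 or CKO 5, with adjusted p up to 0.124.

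Stress genes rose as a set, and some matrix genes rose. Of 29 tested genes of cardiac stress and remodelling 12 rose and 0 fell, with 19 past the threshold when adjusted over the list alone (17 higher and 2 lower). Together the stress genes had a median of 1.08 (camera adjusted p = 2.26e-20; adjusted p = 0.00650 with an estimated correlation). Nppb, the brain natriuretic peptide gene (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205, plus strand), rose from 79.5 ± 20.7 to 331 ± 131 CPM (log2 fold change 2.06, SE 0.33, adjusted p = 0.00799). Xirp1 rose from 140.1 ± 34.4 to 440.4 ± 118 CPM (1.65, SE 0.24). Without Ctrl 1, Ctrl 2, Ctrl 4 or CKO 1 the number of higher members was 6, 5, 7 and 7. Of 59 tested extracellular matrix and fibrosis genes 7 rose and 0 fell, with 32 past the threshold when adjusted over the list alone (31 higher and 1 lower). Matrix genes as a set had a median of 0.60 (camera adjusted p = 3.86e-17; adjusted p = 0.201 with an estimated correlation). Among them were periostin, Postn (154 ± 44.6 to 614 ± 295 CPM, 2.00), the collagens Col8a1 (1.52) and Col4a1 (0.71) and the procollagen peptidase Adamts2 (0.86), and the count was 4, 2 and 3 without Ctrl 1, Ctrl 2 and Ctrl 4. Of 26 tested fibroblast markers 2 rose, Postn and Meox1 (0.88), and 0 fell, with 7 past the threshold when adjusted over the list alone (6 higher and 1 lower). Fibroblast markers had a median of 0.40 (camera adjusted p = 2.6e-05; adjusted p = 0.419 with an estimated correlation). The fibroblast count was 0 without Ctrl 2 or Ctrl 4, and 1 without Ctrl 1, Ctrl 3, CKO 1, CKO 2, CKO 5 or CKO 6. Leaving out the libraries with airway transcripts, Ctrl 3 and CKO 4, left 12 stress and 6 matrix genes higher. Postn missed the threshold without Ctrl 2 or Ctrl 4 (adjusted p up to 0.0601) and Adamts2 without Ctrl 2 (0.0524). Meox1 passed only in the full set and without CKO 3 or CKO 4, with adjusted p up to 0.140.

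Macrophage, interferon, cytokine and complement lists leaned upward by camera at the preset correlation but passed in no case with an estimated one. Of 28 tested macrophage and monocyte markers 4 rose and 0 fell, with 16 past the threshold when adjusted over the list alone (15 higher and 1 lower). Macrophage markers as a set had a median of 0.72 (camera adjusted p = 4.66e-09; adjusted p = 0.234 with an estimated correlation). Called members were the lipid receptor Trem2 (1.54), Cd68 (1.15), the haemoglobin scavenger receptor Cd163 (0.72) and the complement component C1qb (0.83). Leaving out Ctrl 1 to 4 in turn gave 0, 1, 10 and 1 higher, and leaving out CKO 1 to 6 gave 1, 1, 7, 2, 1 and 2, with 2 lower without CKO 4. Of 41 tested interferon response genes 2 rose, Iigp1 (1.23) and Xaf1 (1.55), and 0 fell, with 25 past the threshold when adjusted over the list alone (all higher). Interferon genes had a median of 0.63 (camera adjusted p = 1.54e-15; adjusted p = 0.201 with an estimated correlation). Among 27 tested cytokines and chemokines the monocyte attractants Ccl8 (4.29 ± 1.86 to 25.2 ± 7.95 CPM, 2.54) and Ccl7 (1.71) rose and 0 fell, with 11 past the threshold when adjusted over the list alone (all higher). The cytokine list had a median of 0.66 (camera adjusted p = 4.57e-08; adjusted p = 0.201 with an estimated correlation). Of 21 tested complement genes Masp1 (0.88) and C1qb rose and Clu (-0.77) fell, with 8 past the threshold when adjusted over the list alone. This list had a camera adjusted p of 0.000495 (adjusted p = 0.419 with an estimated correlation). Of 29 tested immediate early genes 5 rose and 0 fell, with 10 past the threshold when adjusted over the list alone. The set had a median of 0.59 (camera adjusted p = 4.06e-10; adjusted p = 0.201 with an estimated correlation). They were Atf3 (20.3 ± 9.77 to 113 ± 53.9 CPM), Cyr61 (1.86), Ier3 (1.10), Ier5 (1.10) and, named after its values were seen, Klf6 (0.59). Their number was 1 without Ctrl 1, 0 without Ctrl 2, and 3 without Ctrl 4, CKO 2, CKO 3, CKO 5 or CKO 6. The interferon count was 1 without Ctrl 1, Ctrl 2, Ctrl 4, CKO 1, CKO 2 or CKO 6, and 6 without CKO 3. Cytokine calls numbered 1 without Ctrl 1, Ctrl 4, CKO 1, CKO 2, CKO 5 or CKO 6, and 4 without Ctrl 3. Complement calls numbered 3 higher without Ctrl 3, 4 without CKO 3, and 1 without any other library. Iigp1, Ccl8 and Masp1 passed without any 1 library. Trem2 did not without Ctrl 1 (adjusted p = 0.0673), nor Ier3 without Ctrl 2 (0.0622). Atf3 and Ier5 missed the threshold without Ctrl 1 or Ctrl 2 (up to 0.0687 and 0.0667). Clu missed it without Ctrl 1, Ctrl 2, Ctrl 4, CKO 2, CKO 3 or CKO 5 (up to 0.113), and Cyr61 without these or CKO 6 (up to 0.112). Cd68 and C1qb passed only in the full set and without Ctrl 3 or CKO 3 (adjusted p up to 0.114 and 0.135 otherwise). For Cd163 the libraries it could spare were Ctrl 3, CKO 4 and CKO 6 (up to 0.133), for Xaf1 CKO 4 and CKO 5 (up to 0.109), and for Ccl7 Ctrl 2 and CKO 3 (up to 0.121).

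The cell division genes that rose did so from low levels. Of 43 tested cell cycle genes 20 rose and 0 fell, with 32 past the threshold when adjusted over the list alone (all higher). As a set the cell cycle genes had a median of 1.43 (camera adjusted p = 5.57e-34; adjusted p = 0.129 with an estimated correlation). Kif11, a motor of the mitotic spindle (ENSMUSG00000012443, chromosome 19, 37376403 to 37421859, plus strand), rose from 2.19 ± 0.689 to 15.3 ± 6.09 CPM (log2 fold change 2.80, SE 0.35, adjusted p = 0.00245). The spindle checkpoint kinase Bub1b (1.28 ± 0.529 to 9.77 ± 4.17 CPM, 2.92), the mitotic kinase Cdk1 (1.32 ± 0.630 to 9.82 ± 4.27 CPM, 2.89) and cyclin B2, Ccnb2 (3.76), rose with it. Outside the list, Dlgap5 (3.62), Kif4 (3.35), Ncaph (2.99) and Cep55 (2.99), all genes of mitosis, were among the 12 largest increases of genes without overlap between the groups and with a mean CPM of 1 or more. The count of 20 was 8 without Ctrl 1, 5 without Ctrl 2 and 12 without Ctrl 4, and 14 without both Ctrl 3 and CKO 4. Ccnb2 missed the threshold without Ctrl 2 (adjusted p = 0.0557). Of 27 tested p53 and DNA damage genes Plk2 (0.91) rose and 0 fell, with 2 past the threshold when adjusted over the list alone. There were 2 calls without CKO 4. The p53 list had a median of 0.11 (camera adjusted p = 0.0234; adjusted p = 0.129 with an estimated correlation).

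**Figure D2:**
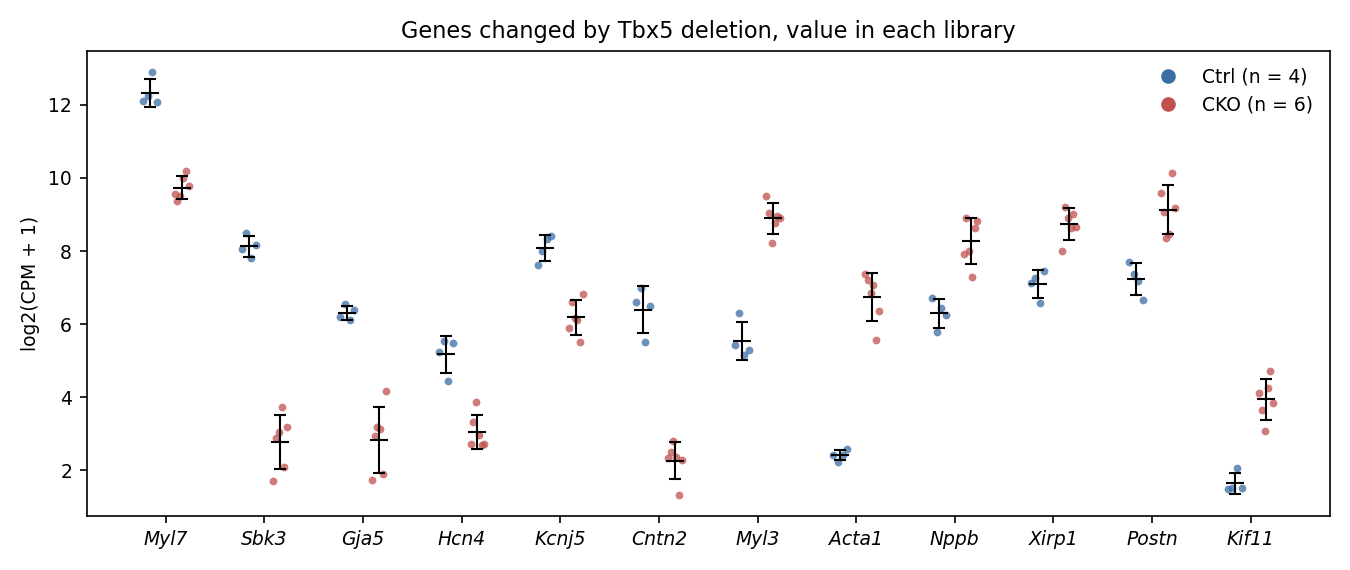
Level of 12 named genes as log2(CPM + 1) in each of 4 Ctrl (blue) and 6 CKO (red) libraries; points are libraries and bars are mean ± SD. The groups do not overlap for Sbk3, Myl7, Gja5 and Cntn2, lower in CKO, nor for Acta1, Myl3 and Kif11, higher in CKO, with Acta1 at 4.34 ± 0.518 CPM in Ctrl and 115 ± 43.7 CPM in CKO.

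Of the metabolic lists, edgeR with adjustment over all genes called a single member, Idh2. Among 69 tested oxidative phosphorylation genes and 43 tested cytosolic ribosomal protein genes 0 were called, by all genes or adjusted over the list alone, though both lists shifted upward as sets. Oxidative phosphorylation had a median of 0.29 (camera adjusted p = 4.62e-09; adjusted p = 0.486 with an estimated correlation). Ribosomal genes had a median of 0.36 (camera adjusted p = 4.13e-09; adjusted p = 0.483 with an estimated correlation). With 1 library left out, 1 oxidative phosphorylation gene was called without Ctrl 1, CKO 3 or CKO 4, and 1 ribosomal gene without Ctrl 3. The abundant ATP synthase genes Atp5b (0.10, SE 0.11) and Atp5a1 (0.01, SE 0.11) and the ribosomal Rpl4 (0.23) and Rplp1 (0.46) did not pass. Of 37 tested genes of the citric acid cycle and branched-chain amino acid breakdown the mitochondrial isocitrate dehydrogenase Idh2 rose (0.51, adjusted p = 0.0250) and was the list's only call (1 adjusted over the list alone; camera adjusted p = 0.379). Fatty acid genes had 0 calls of 44, and 0 adjusted over the list alone (camera adjusted p = 0.379), with Lpl at 0.57 and Pdk4 at 0.18. Glycolysis genes had 0 calls of 30, and 2 adjusted over the list alone (camera adjusted p = 0.615), with Aldoa at 0.10 and Pdha1 at 0.06. Without CKO 6, 1 fatty acid gene was called lower, and without CKO 4, 1 glycolysis gene was called higher. The Xist covariate gave 1 higher fatty acid, 1 higher glycolysis and 1 higher ribosomal gene, a surrogate variable 1 higher glycolysis and 1 higher ribosomal gene, and leaving out Ctrl 3 and CKO 4 gave 1 higher ribosomal gene. At an unadjusted p under 0.05 edgeR gave 20 oxidative phosphorylation, 12 ribosomal, 8 fatty acid and 6 glycolysis genes, and DESeq2 called 2, 1, 3 and 4. Idh2 missed the threshold without Ctrl 1, Ctrl 2, Ctrl 4, CKO 1 or CKO 6 (adjusted p up to 0.0857). The signs of Atp5b, Atp5a1, Aldoa and Pdha1 turned negative on a TPM scale, which shifted the median of all genes to -0.15 with a pseudocount of 1 and -0.17 with 0.1. That of Atp5a1 also turned with library size only and with upper-quartile scaling. Mitochondrially encoded genes were at 0 in every library of the count table and could not be tested.

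Markers of other cell types gave few calls. Vwf, an endothelial clotting protein, rose (667 ± 199 to 1368 ± 249 CPM, 1.04) as 1 of 28 tested vascular endothelial and endocardial markers. Of these 2 passed when adjusted over the list alone, and their median was 0.05, or -0.01 with library size only (camera adjusted p = 0.171). Without Ctrl 3 there were 2 calls. Des was the only called gene of 22 smooth muscle and pericyte markers (1 adjusted over the list alone; camera adjusted p = 0.0522). This list passed camera without Ctrl 3 and CKO 4 (adjusted p = 0.0192), with the Xist covariate (0.0241), a surrogate variable (0.00351), the replicate block (0.00542) and library size only (0.0376). Of 28 tested nerve, ganglion and Schwann cell markers Dbh, the noradrenaline-making enzyme (17.8 ± 4.66 to 4.44 ± 1.80 CPM, -2.0), and Kcna1 (-1.35) fell and Hand2 rose, with 3 past the threshold when adjusted over the list alone. Nerve markers had a median of -0.90 (camera adjusted p = 0.0782, and 0.00628 with DESeq2). Of 32 tested white and brown adipocyte markers Dgat2, an enzyme of triglyceride synthesis, fell (-0.65) and 0 rose, with 1 past the threshold when adjusted over the list alone. Adipocyte markers had a median of -0.45 (camera adjusted p = 0.000176; adjusted p = 0.419 with an estimated correlation). No edgeR call fell among 8 lymphatic endothelial (camera adjusted p = 0.379), 20 epicardial and mesothelial (0.612), 11 neutrophil and mast cell (0.544), 10 lymphocyte (0.233), 14 lung and airway (0.379) and 9 red blood cell markers (0.0631). Adjusted over each list alone 2, 0, 0, 0, 0 and 2 of them passed. At an unadjusted p under 0.05 edgeR gave 3, 0, 1, 0, 3 and 2, and DESeq2 called 1, 0, 0, 0, 0 and 2. Without CKO 1 edgeR called 1 red blood cell marker, with the Xist covariate 2 and with a surrogate variable 1. A surrogate variable also gave 1 lower lymphatic marker, and leaving out Ctrl 3 and CKO 4 gave 1 lower airway marker. Camera passed for red blood cell markers with the Xist covariate (adjusted p = 0.00267), a surrogate variable (0.00443) and library size only (0.0407), and for airway markers with the replicate block (0.0486). Their named members read Stab1 0.55, Lyve1 0.58, Sulf1 0.33, Upk3b -0.03, Cpa3 0.22, Kit 0.28, Ighm -1.40, Igkc -1.52, Bpifa1 0.11, Scgb1a1 0.11, Hbb-bs 1.2 and Tfrc -0.21 in log2 fold change. Bpifa1 and Scgb1a1 rest on Ctrl 3 and CKO 4, and without both their fold changes were -3.31 and -2.81; Upk3b was 0.17 without them. Vwf missed the threshold without Ctrl 1, Ctrl 2, Ctrl 4 or CKO 1 (adjusted p up to 0.098), and Des without Ctrl 2 or Ctrl 4 (up to 0.0593). Kcna1 passed only in the full set and without Ctrl 3 or CKO 2 (up to 0.137), and Dgat2 without Ctrl 3, CKO 3 or CKO 4 (up to 0.110).

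Of 34 tested genes of the unfolded protein response and heat shock Atf3 and Hspb1 (0.78) rose, with 2 past the threshold when adjusted over the list alone. There were 0 calls without Ctrl 1 or Ctrl 2, 2 without CKO 4 and 1 without any other library. The list as a set had a camera adjusted p of 0.0782, which was 0.00346 without Ctrl 3 and CKO 4, 0.0313 with the Xist covariate and 0.0419 with a surrogate variable. Among 24 tested circadian and glucocorticoid response genes the metallothionein Mt2 rose (1.56), with 7 past the threshold when adjusted over the list alone (4 higher and 3 lower). The circadian list had a median of 0.33 (camera adjusted p = 0.0493; adjusted p = 0.419 with an estimated correlation). The list had 3 calls without CKO 4 and 2 without Ctrl 3. Its camera call was lost with DESeq2 (adjusted p = 0.0533), the Xist covariate (0.0827) and a surrogate variable (0.127). Of 50 tested Notch, BMP and Wnt genes the Wnt antagonist Sfrp5 fell (17.1 ± 10.7 to 2.98 ± 1.10 CPM, -2.51) and 0 rose, with 7 past the threshold when adjusted over the list alone (3 higher and 4 lower). The camera adjusted p was 0.875, the median of this list was 0.07 and its mean -0.04, with opposite signs from camera and fry. Without Ctrl 3 or CKO 4 this list had 1 higher call. Ranked within the same limits of level, overlap and name, the 12 largest decreases also held Alox8, a lipoxygenase (-5.19), Aldh3b3 (-4.92), the matrix protein Cilp2 (-3.53), the cadherin Cdh22 (-3.44), Fcamr (-3.38) and the serine dehydratase Sds (-2.70). Among the 12 largest increases within these limits were the transglutaminase Tgm3 (4.11), Parpbp (3.45), Ckap2 (3.25), the histone gene Hist1h2bm (3.21, a transcript class whose capture depends on the selection of RNA, on which labels and description differ) and Pimreg (3.03). Hspb1 passed only in the full set and without CKO 4 (adjusted p up to 0.147), and Tgm3 without CKO 3 or CKO 6 (up to 0.114). Mt2 missed the threshold without Ctrl 1, Ctrl 2, Ctrl 4, CKO 1 or CKO 3 (up to 0.107), and Parpbp without Ctrl 1, Ctrl 4 or CKO 1 (up to 0.0862). Ckap2 did so without Ctrl 2, Ctrl 4, CKO 1, CKO 2 or CKO 6 (up to 0.107), Hist1h2bm without Ctrl 2 (0.0524), and Pimreg without Ctrl 1, Ctrl 2, Ctrl 4 or CKO 1 (up to 0.0702).

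**Figure D3:**
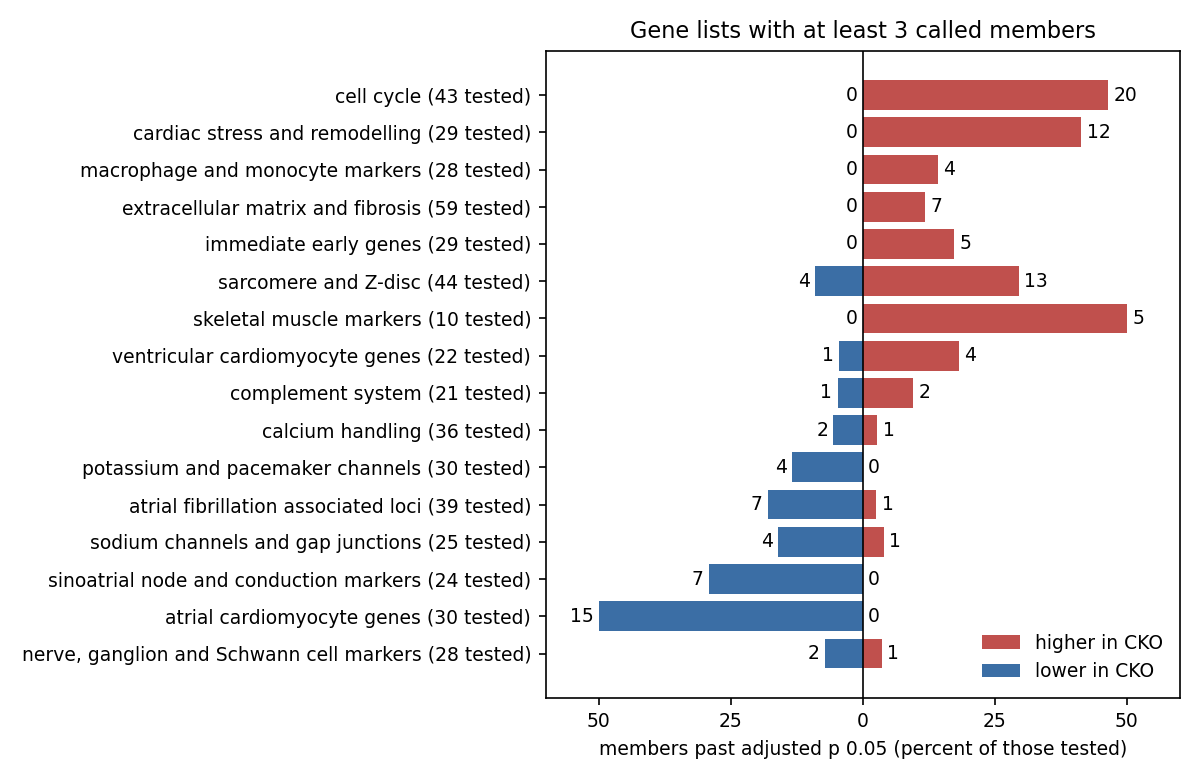
Percent of tested members of each gene list past an adjusted p of 0.05 (edgeR's quasi-likelihood test) and higher (red) or lower (blue) in 6 CKO than in 4 Ctrl libraries, with the number of genes printed at each bar, for lists with at least 3 called members. Atrial cardiomyocyte genes have 15 lower of 30 and 0 higher, and cell cycle genes 20 higher of 43 and 0 lower.

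With camera at a preset correlation of 0.01, 22 of 38 tested lists passed an adjusted p of 0.05, 16 higher and 6 lower. With an estimated correlation 3 did: atrial cardiomyocyte genes (lower), cardiac stress and skeletal muscle markers (higher). By fry, which asks if a list's genes move one way on balance, 14 passed, 11 higher and 3 lower. Chance cannot be excluded for the number of lists past camera at the preset correlation, since 18 of 100 regroupings of the libraries gave as many. The number of called genes was 221, 190 and 237 without Ctrl 1, Ctrl 2 and Ctrl 4, 305 without CKO 1 and 331 without CKO 2. It was 37 with replicate number as a block and 1132 with DESeq2. Of the 78 called genes named by rule, 45 passed without any 1 library. Within the 2 Ctrl and 3 CKO libraries of high Xist level 272 genes were called. Within the 2 Ctrl and 3 CKO libraries of low level 3 were. The low level holds both libraries with airway transcripts, Ctrl 3 and CKO 4, and Ctrl 4, which like them was high in immunoglobulin transcripts. Of the genes called with all libraries, all 496 and 497 that could be tested there kept their sign. Their median absolute log2 fold change was 1.18 at high and 1.17 at low level, so the counts do not show a larger effect at high level. These genes were called on the same libraries, and 460 of the 497 did not overlap between the groups. Most of the kept signs are therefore built in.

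The deposited table of the authors also compares the tissue around the pulmonary veins with the left atrial appendage, the ear-shaped pouch of the same chamber, so that genes that mark each part can be named. In the authors' deposited table many fat, nerve and node-like genes were higher around the pulmonary veins, and so were airway genes, which were most abundant in 1 control. The highest genes there, without clone names, were the airway gene Bpifa1 (15.18 on the log2 scale), the brown fat uncoupling protein Ucp1 (14.48), Scgb1a1 (13.82), the airway cytochrome Cyp2f2 (12.85), and the nerve ending protein Snap25 (10.76). Next in the authors' deposited table came Elovl3 (10.64), the smooth muscle actin Actg2 (9.83), Ces1f (9.75), the fat cell receptor Adrb3 (9.66) and Slc27a2 (9.61). Lowest around the veins in the authors' deposited table, again without clone names, were Uts2b (-8.21), Scgb1c1 (-7.44), Sla2 (-5.65), the growth factor Igf2 (-5.09), Adh6b (-4.79), Ccdc107 (-4.31), Grin2c (-3.28), Adamts8 (-2.83), Nppb (-2.81) and Slco1a4 (-2.44). Some of these values rest on few Ctrl libraries. Bpifa1 was at 2183 CPM in Ctrl 3 and 1.09 to 136 CPM in the other controls, Scgb1a1 at 862 and 0 to 42.0 CPM, and Cyp2f2 at 429 and 1.53 to 28.5 CPM. Snap25 was at 91.8 CPM in Ctrl 4 and 0 to 10.1 CPM in the others. Of its 13646 genes 1671 passed the authors' false discovery rate of 0.05, 1117 higher and 554 lower around the veins. The appendage libraries came from an earlier study, so that region cannot be told apart from study and library batch. The direction was taken from the column name and the counts. The 139 genes with a log2 fold change of 3 or more had a median of 19.2 CPM in the Ctrl libraries here and the 9 genes at -3 or less had 0.479 CPM.

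Node and conduction genes were among those higher around the veins in the authors' deposited table: Cntn2 (7.16), Hcn4 (4.05), the node transcription factor Shox2 (4.62), Cacna2d2 (2.41) and Tbx3 (2.50). Of 22 sinoatrial node and conduction markers 12 were higher and 2 lower (adjusted p = 4.85e-07 in Fisher's exact test over all genes of the table). Adipocyte markers gave 23 of 31 higher (adjusted p = 2.56e-17 in Fisher's exact test), nerve markers 13 of 17 (4.6e-10), extracellular matrix genes 19 of 57 (9.17e-07), and fibroblast markers 12 of 25 (2.06e-06). Further lists were macrophage markers 12 of 28 (8.19e-06), lymphocyte markers 5 of 5 (2.77e-05) and smooth muscle markers 9 of 22 (0.000189). The lymphocyte result rests on 2 controls, with Ighm at 12.5, 18.7, 469 and 961 CPM and Igkc at 1.37, 1.64, 152 and 353 CPM in Ctrl 1 to 4. Atrial cardiomyocyte genes leaned the other way with 11 of 30 lower (adjusted p = 3.07e-07 in Fisher's exact test), as did ventricular cardiomyocyte genes with 8 of 22 (1.29e-05), oxidative phosphorylation with 13 of 69 (2.77e-05) and potassium and pacemaker channels with 8 of 28 (7.33e-05). Single genes lower around the veins in the authors' deposited table included Nppa (-2.13), Gja5 (-1.69), Nkx2-5, a cardiac transcription factor (-1.31), and Sbk2 (-1.38). These fold changes and p-values are the authors' own and were not computed again here, because the appendage libraries belong to another study.

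A comparison of the deletion in both parts of the chamber asks how far the response around the veins is shared with the appendage. In the authors' deposited table a false discovery rate of 0.05 was passed by 750 genes after deletion around the veins (413 higher, 337 lower) and 4732 in the appendage (2292 higher, 2440 lower). Of the 750, 645 were also called in the appendage, 641 in the same direction. Of these 357 were higher in both, where 69.4 would be shared by chance, and 284 lower in both, where 60.3 would. The 4 genes called in opposite directions were Gm30003, Gm42417, Rnu12 and the acid phosphatase Acp5. Across genes, which are not independent replicates, the fold changes of the parts had a Pearson correlation of 0.659, and 524 of the 645 genes (81.2%) had the larger change in the appendage. Their median absolute log2 fold change was 1.63 there and 1.16 around the veins. Cell cycle genes were higher in both in the authors' deposited table, with 26 of 43 around the veins and 41 of 43 in the appendage. Cntn2 changed by -4.48 around the veins and 0.43 in the appendage (false discovery rate 0.685) in that authors' deposited table, and Hcn4 by -2.27 and -0.90 (0.228). Both genes were higher around the veins in the authors' region comparison (7.16 for Cntn2 and 4.05 for Hcn4 on the log2 scale). Their lower level in the appendage leaves less room to measure a decrease there. These differences between parts were not tested. The authors' fold changes around the veins had a Pearson correlation of 1.00 across 13628 genes with those computed here. Of the 464 genes called here that their table holds 423 (91.2%) were called there too, all in the same direction.

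Genes that mark the region were then examined for their response to the deletion, the dependence on Tbx5 that the study's title names. Genes that the authors' deposited table places lower around the veins, which include Gja5, Sbk2, Cilp2 (-2.10) and Angpt1 (-1.61), were over-represented among the genes that fell. They made up 43 of the 201 genes called lower here, where 8.08 would be shared by chance (odds ratio 6.96, adjusted p = 3.05e-19 in a two-sided Fisher's exact test over 13628 genes). They were also over-represented among the genes that rose, with 28 of 263 against 10.6 (odds ratio 2.94, adjusted p = 5.16e-06 in Fisher's exact test), among them Nppb and Myl3 (-1.62). Genes higher around the veins, such as Cntn2, Hcn4, Alox8 (6.33 in the authors' deposited table) and Dbh (2.43), gave 20 of 201 among those lower after deletion (16.5 by chance, odds ratio 1.24, adjusted p = 0.363 in Fisher's exact test). Among those higher after deletion they gave 16 of 263 (21.5 by chance, odds ratio 0.722, adjusted p = 0.34 in the same exact test). When only genes with a regional difference of at least 1 on the log2 scale were kept, 17 genes were higher around the veins and lower after deletion, against 10.2 by chance (odds ratio 1.74, adjusted p = 0.0468 in Fisher's exact test). With deletion calls at an adjusted p under 0.01 instead, 9 were, against 6.88 by chance (odds ratio 1.35, adjusted p = 0.42 in Fisher's exact test). As sets, the 1116 genes higher around the veins had a median log2 fold change of -0.10 and the 548 lower ones 0.14 (camera adjusted p = 0.134 for both). The Ctrl libraries enter both comparisons, which alone gives a negative relation. The covariance of the fold changes was -0.0642, and the shared libraries alone would give -0.0517 as computed from their variance or -0.0473 ± 0.00714 (SD) in 20 simulations.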

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

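The tests of the Tbx5 total, of Myl3 and Acta1 and of the cell cycle genes, the fits without Ctrl 3 and CKO 4 and the contrast by Xist level were chosen after the results were seen. A single library stood apart from the rest of its group, by Dixon's test of the gap over the range at 95%, in 26 of 218 groups of 4 or 6 values, where chance gives about 1 in 20, or 10.9. Ctrl 3 accounted for 7 of these, CKO 4 for 6, CKO 5 and Ctrl 2 for 4 each, Ctrl 4 for 3, and CKO 3 and CKO 6 for 1 each.

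Airway genes marked Ctrl 3 and CKO 4, and immunoglobulin genes these and Ctrl 4. Bpifa1 was at 2183 CPM in Ctrl 3 (other controls 1.09 to 136) and 3739 CPM in CKO 4 (other CKO 0 to 16.4), and Scgb1a1 at 862 CPM in Ctrl 3 (0 to 42.0) and 1452 CPM in CKO 4 (0 to 7.97). In CKO 4 the immunoglobulin genes Ighm (658 CPM, others 22.4 to 53.5) and Igkc (226 CPM, others 2.15 to 17.9), the mast cell gene Cpa3 (18.8 CPM, others 8.90 to 11.5) and Scn10a (0.910 CPM, others 0.210 to 0.452) were high. In Ctrl 1 to 4 Ighm was at 12.5, 18.7, 469 and 961 CPM and Igkc at 1.37, 1.64, 152 and 353 CPM. Ctrl 3 was high for Myl7 (7654 CPM, others 4322 to 4859), Rpl4 (585 CPM, others 423 to 432) and Kif11 (3.22 CPM, others 1.80 to 1.88), and low for Kcnj3 (155 CPM, others 224 to 234) and Pimreg (0, others 0.775 to 0.874 CPM). CKO 5 was high for Lyve1 (232 CPM, others 92.3 to 129.6), Sulf1 (392 CPM, others 174 to 243), Kif20a (17.9 CPM, others 6.15 to 9.62) and Rplp1 (754 CPM, others 391 to 522). Ctrl 4 was low for Col8a1 (38 CPM, others 59.7 to 63.6) and Adamts2 (96.8 CPM, others 134 to 138) and high for Hist1h2bm (1.33 CPM, others 0.423 to 0.546). Myl3 was high in Ctrl 2 (78.2 CPM, others 34.9 to 41.7) and Iigp1 in CKO 6 (104.9 CPM, others 56.9 to 69.9).

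Main-transcript exon ratios of Tbx5 stood apart in Ctrl 2 for exon 6 (0.566, others 1.17 to 1.28), exon 8 (2.44, others 1.00 to 1.19) and exon 9 (1.21, others 0.493 to 0.561), and in CKO 3 for exon 4 (0.586, others 0.990 to 1.15). A test of the genotype effect between high and low Xist level gave 1 gene past an adjusted p of 0.05, Tmem170b, with a difference of 4.29 on the log2 scale (adjusted p = 0.000861), and 911 genes at an unadjusted p under 0.05. Tmem170b (chromosome 13, 41605907 to 41641355) was at 59.3 and 54.6 CPM in Ctrl 1 and 2, at 2.67 and 3.10 CPM in Ctrl 3 and 4, and at 43.1 to 59.5 CPM in the 6 CKO libraries.

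Total Tbx5 RNA was higher in the CKO libraries, without passing the threshold except with DESeq2 (adjusted p = 0.00963) and the Xist covariate (0.0116). Swapped genotype labels are argued against by exon 3, taken from general knowledge to be the exon that recombination removes, since the highest CKO ratio of 0.618 lay below the lowest Ctrl ratio of 0.903. Library scaling is argued against by the lowest fold change of 0.94 (log2) among RLE, upper-quartile and library-size scaling. More full-length messenger RNA would raise exon 3 with the other exons. Scaled to library size, exon 3 coverage in CKO was 0.711 of that in Ctrl while exon 8 was at 2.11 times. On that scale exon 3 overlapped between the groups (2.49 ± 1.01 in Ctrl and 1.77 ± 0.951 in CKO) and 0 exons passed, so it cannot decide. The exon 3 ratios to the median exon, which did not overlap, argue against full-length RNA as the only source of the rise. As a hypothesis, transcripts without exon 3 may accumulate after recombination. Exon 1 coverage scaled to library size was 1.02 times that in Ctrl, whereas accumulation of transcripts lacking only exon 3 would raise it too. Whether such transcripts would accumulate through their synthesis or their decay was not tested.

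Myl3 and Acta1 rose in CKO. Ventricular muscle in the dissections would bring Myl2, as abundant there as Myl3, yet the rise of Myl2 was at most 21.7% of that of Myl3 in a CKO library (CKO 2) and at most 3.48% in the others, with Myl2 at 4.05 ± 4.31 CPM in Ctrl and 7.68 to 107 CPM in CKO. Skeletal muscle would bring its fast fibre genes. The summed change of Tnnt3, Tnni2, Mylpf, Atp2a1 and the fast myosins was at most -1.59% of the rise of Acta1. The myosins Myh1, Myh2 and Myh4 were at 0 in every library and so add nothing to this sum. For these, removal of similar sequences cannot be ruled out. The summed set was chosen after the results were seen. It leaves out Casq1, Mybpc2, Ckm and Myl1, skeletal muscle markers that rose, so skeletal muscle is argued against only by the genes summed. A change in atrial muscle itself stays a hypothesis, which no cell-resolved value here can test.

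In CKO 20 of 43 tested cell cycle genes were called higher, though the list did not pass camera with an estimated correlation (adjusted p = 0.129). A lower share of cardiomyocytes, acting alone, would raise the markers of all other cell types alike. The macrophage median exceeded the endothelial median by 0.67 on the log2 scale, 4.21 times the standard error over genes, which treats genes as independent. Nerve and adipocyte marker medians were negative (-0.90 and -0.45). Among the controls the nerve gene Snap25 was high in Ctrl 4 alone, so the nerve median may partly reflect that library. With replicate number as a block the nerve median was -0.16 and the adipocyte median -0.74. The macrophage list did not pass camera with an estimated correlation. A lower share joined by changes in single cell types could give the same values, so these cannot exclude it. Libraries with airway, lymphoid or nerve transcripts do not carry the rise by themselves: 14 genes were called without Ctrl 3 and CKO 4, all among the 20, and 12 without Ctrl 4, 11 of them among the 20, with medians of the list at 1.39 and 1.46, though 8 were called without Ctrl 1 and 5 without Ctrl 2. More dividing cells after deletion could give such a rise; which cell type divides stays open.

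Of 100 divisions of the libraries into 4 and 6, the real one included, 1 gave as many called genes as the genotypes. That was the real one, with 497 genes, against 130 in the next highest. As the real one is always counted, 1 of 100 is the smallest share possible, so chance is unlikely but not excluded. The other divisions mix the genotypes, so a true genotype effect adds to their spread and can lower their counts. The same holds for the 274 higher genes (1 of 100, next highest 19), the 223 lower genes (1 of 100, next highest 111) and the 3 lists past camera with an estimated correlation (1 of 100, next highest 0). For the 22 lists past camera at the preset correlation chance cannot be excluded, since 18 of 100 divisions gave as many and the highest gave 27. The division with 130 genes set Ctrl 3, Ctrl 4, CKO 4 and CKO 5 against the others. All 4 were of low Xist level, but CKO 6, also of low level, was among the others. Ctrl 3 and CKO 4 also held airway transcripts, and these and Ctrl 4 immunoglobulin transcripts, so the division does not single out Xist.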

How the results depend on the processing

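The fits without Ctrl 3 and CKO 4 and with the Xist covariate and the exon coverage summed over transcripts were chosen after the data were seen, and the other alternatives before. Of 98 named genes besides Tbx5, 78 were called; in 27 settings 0 of these reversed, and 13 stayed past the threshold in all of them, the replicate block being the setting that ended most. All called genes that could be tested kept their sign in every setting except the TPM scales, where 495 of 497 did. The settings share the libraries on which the genes were called, so kept signs do not show that a change would repeat. Where no reason is given below, the cause was not tested. Depth limits genes of few counts: in the group with the lower mean, counting variance exceeded the fitted dispersion between animals in 929 of 17752 tested genes (5.23%) and in 42 of the 497 called (8.45%). The same held for 1 of 43 cell cycle genes (2.33%) and 1 of the 20 called ones. At 4 against 6 the simulated test found 38.8% of 2-fold changes.

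With DESeq2 1132 genes were called, 692 higher and 440 lower, and Tbx5 passed (1.02, adjusted p = 0.00963); over all alternatives its adjusted p ran from 0.00963 to 0.302. Stricter and looser thresholds by construction gave 141 (52 higher, 89 lower) at 0.01, 854 (484 higher, 370 lower) at 0.1 and 278 (146 higher, 132 lower) against a fold of 1.2. The replicate block, in which CKO 5 and 6 carry no weight and the numbers do not pair, gave 37 (11 higher, 26 lower). Without a low-count filter, with 33196 genes tested, 147 were lower. The surrogate variable gave 346 lower. On the TPM scales 179 (pseudocount 1) and 168 (0.1) were higher, with the median of all genes at -0.15 and -0.17. With the Xist covariate Tbx5 passed (0.94, adjusted p = 0.0116). Camera with an estimated correlation called 3 lists, and fry 14.

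Genes that were not called changed sign as follows. Atp5a1 was -0.0100 with upper-quartile scaling, -0.0513 with library size only, -0.0178 with the surrogate variable, -0.20 on both TPM scales and -0.0125 without Ctrl 3 and CKO 4. On both TPM scales Atp5b, Aldoa and Pdha1 were -0.0661, -0.0680 and -0.0741 with pseudocount 1 and -0.0661, -0.0680 and -0.0742 with 0.1. Upk3b was 0.00751 without a filter, 0.0685 with the surrogate variable and 0.17 without Ctrl 3 and CKO 4, where Pdk4 was -0.16. Bpifa1 and Scgb1a1, which rest on these libraries, were -3.40 and -2.06 with limma-voom, -7.28 and -5.59 with the block, -1.63 and -1.24 with the surrogate variable, -2.48 and -2.0 on the TPM scale with pseudocount 1, -3.58 and -2.34 with 0.1, -3.31 and -2.81 without Ctrl 3 and CKO 4, and -3.36 and -2.13 with the Xist covariate.

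Scaled by the transcript mean, 2 Tbx5 exons passed, and the differences of exon 4 (-0.113) and exon 5 (-0.138) changed sign. Scaled by library total 0 passed, and exon 1 (0.0114), exon 2 (1.5) and exon 7 (1.62) changed sign, since that scale keeps the rise of the whole transcript. Summed over transcripts 4 passed and exon 2 was 0.0306. In the authors' region comparison 1107 genes passed 0.01 and 881 also had a log2 fold change of at least 1 in size, fewer by construction. Without each library in turn the ranges were 190 to 607 called genes (190 without Ctrl 2, 607 without Ctrl 3), 87 to 302 higher, 103 to 314 lower, 20 to 27 lists, 0.82 to 1.11 for Tbx5 and 0 to 2 exons, where a single exon cannot pass with so few libraries. Signs changed for Upk3b (-0.26 to 0.20), Cpa3 (-0.00300 to 0.47), Atp5a1 (-0.0403 to 0.0856), Pdk4 (-0.0859 to 0.64), Bpifa1 (-6.95 to 3.75), Scgb1a1 (-6.74 to 4.04), Tfrc (-0.42 to 0.14) and exons 2 (-0.129 to 0.138), 5 (-0.0395 to 0.221) and 7 (-0.521 to 0.128).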

Other observations

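No test in this part was chosen only after its result was seen, and the single genes given here were named by rule. In the authors' deposited table further groups differed between the tissue around the veins and the appendage, with region and study not separable. Fat genes such as the lipid droplet protein Plin1 (5.71 on the log2 scale), the adipsin gene Cfd (5.02) and Thrsp (3.39), smooth muscle genes such as Myh11 (4.58) and Cnn1 (5.01), and the mast cell chymase Cma1 (9.12) were higher around the veins. So were the signalling genes Bmp10 (7.06) and Bmp2 (2.12), with 12 of 39 Notch, BMP and Wnt genes higher (adjusted p = 0.000243 in Fisher's exact test). The other groups with more higher members than chance in Fisher's exact test were neutrophil and mast cell markers (5 of 7, adjusted p = 0.000337), stress genes (9 of 28, 0.00125), complement (7 of 20, 0.00323), cytokines (7 of 21, 0.00426), and lymphatic and lung markers (4 of 8 each, 0.00865). Lung genes such as Bpifa1 rest mostly on Ctrl 3, at 2183 CPM against at most 136 CPM in the other controls. Lower around the veins were sarcomere genes (9 of 43, adjusted p = 0.00025 in Fisher's exact test) and sodium channel and gap junction genes (5 of 23, 0.00794). Endothelial markers followed (5 of 26, 0.0121). Higher members of these lists numbered 4, 3 and 2. Of 34 cardiac transcription factors 5 were lower (adjusted p = 0.036 in Fisher's exact test), but 6 were higher (0.14).

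DNA of another mouse strain that travels with the floxed allele could change genes near Tbx5. Within 10 Mb of Tbx5, 9 of 286 tested genes were called (3.15%), against 2.79% elsewhere (one-sided Fisher's exact p = 0.408). The 95% exact bounds of that share, 1.45% to 5.89%, reach 2.11 times the share elsewhere, so a small effect of such DNA cannot be told apart from none with 9 genes. The 9 were Sds, Rbm19, Tesc, Cryba4, Gltp, Pxn, Kntc1, Cux2 and Tbx3.

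A second hypothesis was that deletion erodes the regional profile, which would make the covariance of the regional and deletion fold changes more negative than the shared Ctrl libraries alone make it. The covariance was -0.0642, against -0.0517 computed from the shared libraries and -0.0473 ± 0.00714 (SD, 20 simulations), and the difference from the computed value was -1.49 times its standard error of 0.00843 over genes. From the mean of the simulations it was -2.0 standard errors or -2.37 SD, with 0 of 20 simulations as low (lowest -0.0608). The baselines thus differ in what they allow, and both the standard error and the simulations ignore the correlation between genes, so erosion and no erosion cannot be told apart by these values. Across genes the Pearson correlation was -0.172, and -0.203 in the simulations without any effect of deletion. In these at most 1 gene was called and 0 overlapped the regional genes. So few calls left almost no room for overlap, so the 0 does not show what the shared libraries add to the overlaps found.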
